A study of Mus musculus with 8 samples.

How the data were processed

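RNA abundance was measured in CD8+ T cells isolated from mouse spleen, the cytotoxic class of T lymphocytes, 30 h after stimulation with an antigen described as high affinity (2 pmol of M9C, a name the labels do not spell out). Inhibitors were added at 9 h and were present for the remaining 21 h: trametinib at 1 uM, which inhibits MEK, the kinase that activates Erk; cyclosporin A (CsA) at 1 uM, which inhibits calcineurin, the phosphatase that sends NFAT to the nucleus; both compounds together; or the solvent DMSO at 0.1%. The 8 libraries fall into 4 groups of 2. Per the labels' protocols, total RNA was purified from Trizol lysates with a column kit, and an outside company made and sequenced the libraries. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

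The deposited values are estimated counts and TPM per transcript, with lengths and effective lengths, per the file headers. The submitters' processing notes name kallisto 0.46.1 and sleuth 0.30.0 and the builds GRCm38 and mm10; the transcript index and the program settings are not given in the sources used here. TPM values were not tested, since TPM keeps no depth. The 2 files of each library hold one quantification: their largest relative difference was 4.99e-06. Of 118489 transcripts, 116816 (98.6%) matched the GENCODE M21 annotation of GRCm38 with their version. The other 1673 transcripts, which held between 0.712% and 0.755% of the counts of a library, were left out. Estimated counts were summed over the transcripts of 36047 genes and rounded to whole numbers. Kallisto shares reads among similar transcripts by a model, so values of close paralogs (the granzymes, the Klr receptors, Ccl3 and Ccl4, the Ifit genes) carry an uncertainty that the counts do not show, and strand handling is not given in the sources used here.

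Library totals ranged from 21.5 M to 29.5 M estimated counts. Mitochondrial genes took 2.37 to 3.10% of the counts and ribosomal protein genes 6.75 to 9.78%. Replicates were not copies of one library: the chi-square per degree of freedom between replicates was 11.6 for DMSO, 10.2 for trametinib, 41.0 for CsA and 36.4 for the combination. The correlation of log2 CPM between replicates, across genes, lay between 0.982 and 0.987.

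Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which left 13734 genes, and libraries were scaled by TMM. The quasi-likelihood F test was run on all 8 libraries with group as the sole factor. The groups thus shared 1 estimate of spread (common biological coefficient of variation 0.142, 4 residual degrees of freedom). This assumes equal spread in all groups, although replicates differed more with CsA and with the combination than in the other groups. P-values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons, with 0.05 as the threshold: each treatment against DMSO, the combination against each inhibitor alone, trametinib against CsA, and the interaction. The interaction is the trametinib change with CsA present minus the trametinib change without it, on the log2 scale. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values are from edgeR's cpm function on TMM-scaled totals, given as mean ± SD of 2 libraries. Genes with very low counts are described by counts against a floor of 3 counts summed over the 2 libraries of a group. This floor and the intervals of summed counts cover counting error only. On simulated counts for the trametinib comparison with 13734 genes, the test recovered 66% of 100 genes changed by 1 on the log2 scale and 93% of 100 genes changed by 2, with 13 false calls among the unchanged genes.

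Before the data were examined, 23 gene lists, the rule for named genes, the tests and the alternatives were fixed, except for 2 alternatives given below. The lists were genes induced by Erk, genes induced by NFAT, activation surface proteins, inhibitory receptors, cytokines, cytotoxic genes, naive and memory genes, effector transcription factors, DNA replication, mitosis, ribosome biogenesis, glycolysis, cholesterol synthesis, Atf4 targets, the Bcl2 family, the interferon response, T cell identity, and markers of B cells, myeloid cells, dendritic cells, NK cells, CD4 and regulatory T cells, and red cells with platelets. Egr2 and Egr3 stand in both the Erk and the NFAT list, and the NFAT and cytokine lists share several cytokines. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists. No list passed in any of the 7 comparisons when camera estimated the correlation within each list instead. That setting also cuts the degrees of freedom of camera to the residual ones, so a list is harder to pass at any correlation. For T cell identity, combination against trametinib, the unadjusted camera p went from 0.000532 to 0.0448 at an estimated correlation of 0.046. A lost call therefore does not measure correlation alone. On simulated data for the CsA comparison with 13734 genes, camera called a list of 20 shifted genes and 1 of 100 unshifted lists had an unadjusted p below 0.05. The simulated genes were drawn independently. This rate therefore does not cover lists of correlated genes, such as ribosome biogenesis (estimated correlation 0.637).

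Named genes are, per comparison, the 8 largest increases and the 8 largest decreases among genes past the test with a mean log2 CPM of at least 3 in which both libraries of one group lay above both of the other; Gm and Rik gene models and pseudogenes were not named. For the interaction the separation of libraries was not asked. Added to these are genes named in advance (Dusp6, Spry1, Rcan1, Nfatc1, Egr1, Egr2, Myc, Cd69, Pdcd1, Il2ra, Gzmb, Ifng and Tcf7 among them), up to 4 members of each list by adjusted p, and cell type markers with a mean log2 CPM of at least 1. Where this rule does not cover a named gene (Fgl2, Klrc1, Il2, Xcl1, Cd8a and the list members below the count filter), it was chosen after its values were seen. Some genes that the rule takes are not reported here.

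The replicate numbers of the labels occur in all groups. Libraries with the same number deviated from their group means together in all 6 pairs of groups (correlation across genes 0.123 to 0.284), and of 8 ways to swap numbers within groups, 1 gave correlations above 0.1 in every pair. With 2 libraries per group a swap only turns the sign of that group's correlations. Once 1 order is positive in every pair, no other can be, so the count of swaps adds nothing. The check therefore does not establish that the numbers pair the samples, and the labels do not say what a shared number marks. The fit with the replicate number as a block is given beside counts that it moved by over 1.5 times. All calls of named genes and lists that it changed are in the closing section. Both single-inhibitor comparisons use the same DMSO libraries, so their overlap was set beside 20 simulations of unchanged groups. In these all libraries, DMSO included, were redrawn around the DMSO means, and both comparisons shared the redrawn DMSO group. Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, counts scaled by effective length, the second file of each library, fits of the compared groups alone, the replicate block, the estimated correlation, and leaving out each library in turn; the estimated correlation together with the replicate block, and each single inhibitor against a DMSO library of its own, were added after the data were seen. Leaving out 1 library leaves a group with a lone sample, which is then assumed to vary like the other groups. Intervals and permutation tests were computed in Python 3.11.15 with scipy 1.17.1.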

Results

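CD8+ T cells from mouse spleen were stimulated with antigen and, 9 h later, given the MEK inhibitor trametinib, the calcineurin inhibitor CsA, both, or DMSO for a further 21 h. RNA was sequenced from 2 libraries per group. The DMSO libraries held 29.5 M and 23.3 M estimated counts and the trametinib libraries 24.1 M and 25.2 M. The CsA libraries held 22.0 M and 21.9 M and the combination libraries 24.7 M and 21.5 M. The series title names the long-term dynamics of Erk and NFAT signalling as the subject. The comparisons ask which transcripts changed when MEK, calcineurin or both were inhibited after the antigen had acted for 9 h. Errors of log2 fold changes are standard errors, errors of CPM are SD, and n = 2 libraries per group throughout.

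In the DMSO libraries Cd8a, the alpha chain of the CD8 coreceptor, stood at 564 ± 60.9 CPM and Cd8b1, its beta chain, at 295 ± 29.6 CPM. Markers of other cells were near the floor: Cd4 had 2 to 13 counts per library over all 8 libraries and the B cell marker Ms4a1 at most 8. The monocyte gene Csf1r had at most 4 and the NK cell genes Ncr1 and Klrb1c at most 7 and 10. Ighm, the immunoglobulin mu chain, stood higher, at 339 ± 2.00 CPM in DMSO libraries and 785 ± 15.0 CPM with both inhibitors. Cd74, the class II invariant chain, stood at 28.7 ± 4.02 CPM in DMSO libraries and 14.0 ± 1.46 CPM with trametinib. Igkc, the kappa chain, stood at 1.46 to 4.81 CPM per library.

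With trametinib alone Dusp6, Egr1 and Egr2 fell, while Klf2 and S1pr1 rose. Dusp6, a phosphatase of Erk (chromosome 10, 99263231 to 99267489, GRCm38), went from 98.8 ± 8.87 CPM to 7.75 ± 7.93 CPM, a log2 fold change of -3.67 ± 0.59 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00673). Egr1, an early-response transcription factor (chromosome 18, 34859823 to 34864984), fell by 3.55 ± 0.61 and its relative Egr2 by 3.42 ± 0.47 on the log2 scale. In the other direction Klf2, a transcription factor of resting T cells (chromosome 8, 72319033 to 72321656), rose from 14.8 ± 3.07 to 115 ± 9.01 CPM (log2 fold change 2.95 ± 0.18), and S1pr1, the receptor for lymph node exit, rose by 3.06 ± 0.31. Rcan1, a calcineurin regulator and NFAT target, stood at 7.95 ± 0.0675 CPM in DMSO libraries and 9.89 ± 0.225 CPM with trametinib (log2 fold change 0.32 ± 0.17, adjusted p = 0.308 in edgeR's quasi-likelihood test).

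Of the 20 genes on the Erk list, 15 fell with trametinib and none rose, also 15 and none adjusted over the list alone. The median log2 fold change was -2.10 (camera, adjusted p = 9.68e-10; adjusted p = 0.312 with an estimated correlation). Among them Dusp4, a second Erk-pathway phosphatase, fell by 3.42 ± 0.53, and the Ras-Erk inhibitors Spred1 and Spry1 by 2.19 ± 0.30 and 1.42 ± 0.13. Myc was at -0.19 ± 0.12 and did not pass the test. The 2 trametinib libraries stood apart on this list: Dusp6 had 324 and 54 counts in them, against 2659 and 2379 in the DMSO libraries. Of 19 tested NFAT targets, 10 fell and none rose, or 14 fell and 2 rose adjusted over the list alone (camera, adjusted p = 1.03e-06; adjusted p = 0.312 with an estimated correlation). These included the chemokines Ccl3 (-2.39 ± 0.34) and Ccl4 (-1.91 ± 0.28) and the cytokine Tnf (-1.62 ± 0.15), whereas Ifng was at 0.60 ± 0.22 and did not pass. Il2, the T cell growth factor, had 630 and 475 counts in the DMSO libraries and 115 and 6 counts with trametinib. Of 19 cytokines tested, 8 fell and 1 rose, or 12 and 2 adjusted over the list alone (median -1.19; camera, adjusted p = 1.28e-06; adjusted p = 0.600 with an estimated correlation).

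Of 22 naive and memory genes, 10 rose and 1 fell with trametinib, or 13 and 3 adjusted over the list alone (median 0.48; camera, adjusted p = 0.000488; adjusted p = 0.656 with an estimated correlation). Il7r, a cytokine receptor chain, rose by 1.69 ± 0.16 and Ccr7, a lymph node homing receptor, by 1.32 ± 0.09. Among 18 activation surface proteins 7 fell and 1 rose, the same counts adjusted over the list alone (camera, adjusted p = 0.00113; adjusted p = 0.600 with an estimated correlation). They included Cd200 (-1.62 ± 0.17, not past the test with length-scaled counts) and the early activation antigen Cd69 (-1.53 ± 0.17). The inhibitory receptors split: 5 of 16 fell and 1 rose, or 5 and 3 adjusted over the list alone (camera, adjusted p = 0.374). Btla fell by 1.13 ± 0.16 and Ctla4, which regulatory T cells also express, rose by 1.55 ± 0.18. Of 4 CD4 and regulatory T cell markers 2 rose and none fell, or 3 and 1 adjusted over the list alone (camera, adjusted p = 0.156). They were Foxp3 (2.59 ± 0.43, 19 counts over both DMSO libraries and 112 with trametinib) and Ikzf4 (1.26 ± 0.23), both transcription factors of regulatory T cells. Both missed the threshold without DMSO replicate 1 (adjusted p = 0.0863 and 0.0741), DMSO replicate 2 (0.0609 and 0.0991) or trametinib replicate 2 (0.0736 and 0.0941) and with length-scaled counts (0.101 and 0.111). The list passed camera without DMSO replicate 1 (0.0206) or trametinib replicate 1 (0.00768) and with no filter on low counts (0.0222). Of 12 cytotoxic genes 4 fell and 3 rose, or 5 and 5 adjusted over the list alone (camera, adjusted p = 0.428). Prf1, the pore-forming perforin, fell by 2.23 ± 0.26. Prdm1, a transcription factor of effector cells, rose by 3.97 ± 0.38. On its list of effector transcription factors 4 of 22 members rose and 4 fell (5 and 7 adjusted over the list alone; camera, adjusted p = 0.711). Ribosome biogenesis genes lay lower as a group (median -0.28; camera, adjusted p = 6.87e-06; adjusted p = 0.656 with an estimated correlation), though 1 of 26 passed on its own, also 1 adjusted over the list alone. Interferon-response genes lay higher as a group with trametinib as well: 5 of 23 rose and 1 fell, the same adjusted over the list alone (median 0.35; camera, adjusted p = 0.00935; adjusted p = 0.656 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 1.08 ± 0.12. Rsad2, an antiviral enzyme, rose from 6 counts over both DMSO libraries to 123 with trametinib (adjusted p = 0.00527, and 0.0631 without DMSO replicate 1). Mitosis genes passed camera with 1 of 24 rising, also 1 adjusted over the list alone (adjusted p = 0.0420; adjusted p = 0.656 with an estimated correlation). That list missed the threshold without DMSO replicate 1 (0.0662) or 2 (0.133), trametinib replicate 1 (0.117) or 2 (0.0534), with no filter on low counts (0.0503) and with length-scaled counts (0.0856). None of 18 glycolysis genes passed edgeR's test, nor any adjusted over the list alone (camera, adjusted p = 0.197). Of these, 4 had an unadjusted p below 0.05 and DESeq2 called 3. Among markers of other cells, 1 of 6 B cell, 1 of 6 myeloid and 1 of 4 NK markers rose and none fell. Adjusted over each list alone 2, 1 and 1 rose (camera, adjusted p = 0.449, 0.573 and 0.428). Of 8 dendritic cell markers 1 fell and none rose, the same adjusted over the list alone (camera, adjusted p = 0.3745).

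Over all 13734 genes, trametinib raised 731 and lowered 482, of which 353 and 207 changed by over 2-fold. Without DMSO replicate 1 these counts were 231 and 138 and without DMSO replicate 2 they were 237 and 149. Without trametinib replicate 1 they were 362 and 264, without trametinib replicate 2 274 and 128, and with the replicate number as a block 1170 and 937.

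**Figure D1:**
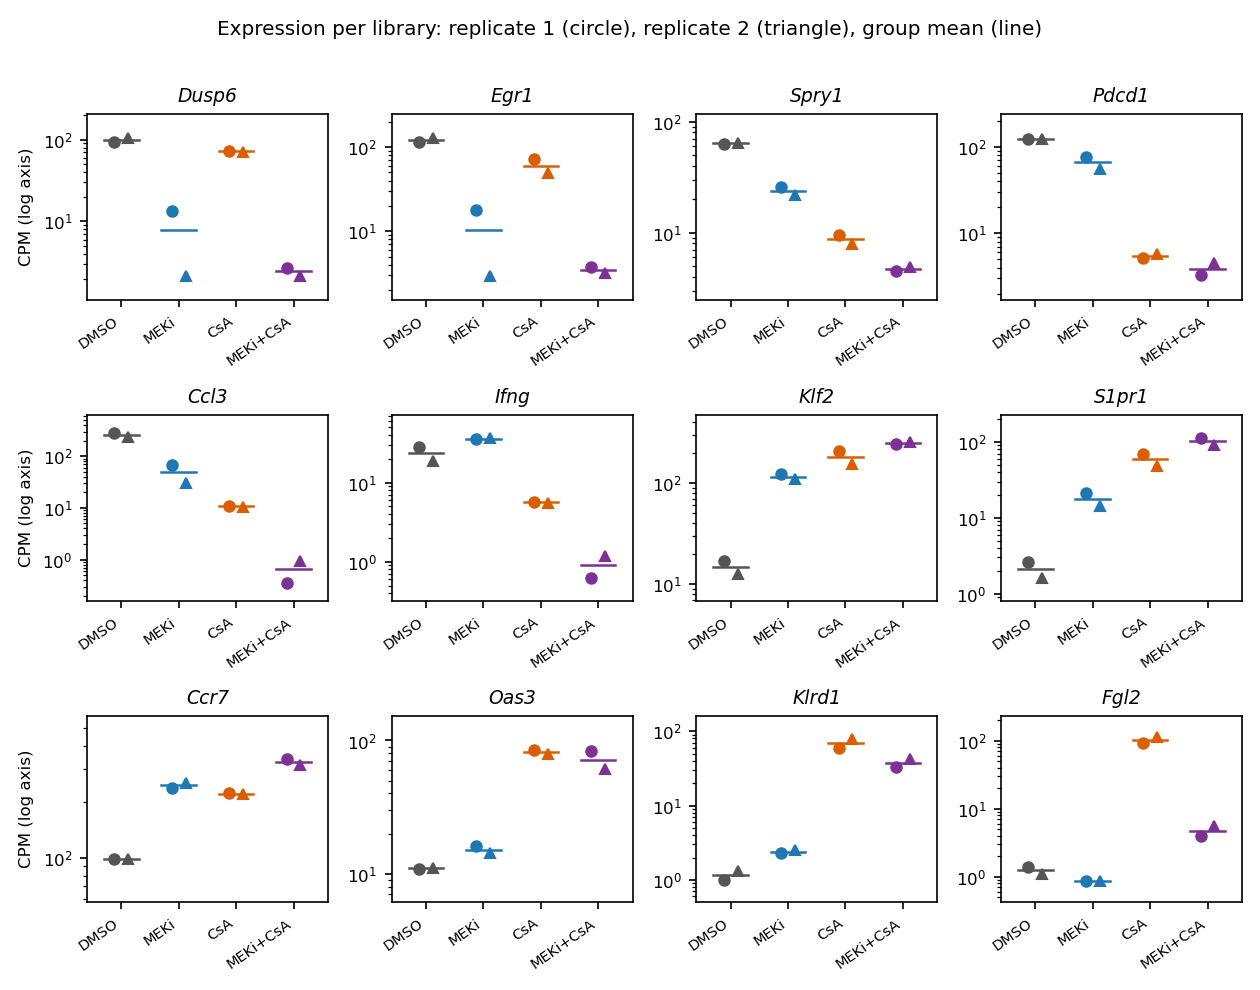
CPM (log axis) of 12 genes in each of the 8 libraries, with replicate 1 as circles, replicate 2 as triangles and lines at the group means. Dusp6 and Egr1 were low in the libraries with the MEK inhibitor (MEKi), Pdcd1 in those with CsA, and Fgl2 was high with CsA alone.

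With CsA alone the surface protein genes Cd200 and Pdcd1 and the chemokines Ccl3 and Ccl4 fell, while Dusp6 did not pass the test. Pdcd1, an inhibitory receptor of activated T cells (chromosome 1, 94038305 to 94052553, GRCm38), went from 125 ± 0.222 to 5.42 ± 0.426 CPM, a log2 fold change of -4.53 ± 0.20 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.26e-06). Cd200 (chromosome 16, 45382135 to 45409053) fell by 5.49 ± 0.21 on the log2 scale and Ccl3 had a log2 fold change of -4.59 ± 0.38. Klrd1, a lectin-like receptor chain of NK cells and some CD8+ T cells (chromosome 6, 129591782 to 129598775), rose from 1.17 ± 0.223 to 69.5 ± 13.7 CPM (log2 fold change 5.91 ± 0.24). Lmna, which encodes the A-type nuclear lamins, rose from 1.55 ± 0.426 to 204 ± 2.99 CPM (7.05 ± 0.36). Dusp6 stood at 71.7 ± 0.600 CPM with CsA (log2 fold change -0.46 ± 0.51, adjusted p = 0.580 in edgeR's quasi-likelihood test). It passed without trametinib replicate 1 or 2 (adjusted p = 0.0448 and 0.0464), with the DMSO and CsA libraries alone in the fit (0.0264) and with no filter on low counts (0.00409).

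Of 19 NFAT targets, 12 fell and 1 rose with CsA, or 13 and 1 adjusted over the list alone (median -1.42; camera, adjusted p = 6.73e-07; adjusted p = 0.306 with an estimated correlation). Nr4a3, a nuclear receptor induced through the T cell receptor, fell by 3.09 ± 0.24, Ifng by 2.08 ± 0.24, Nfatc1, which encodes an NFAT protein, by 1.42 ± 0.19 and Irf4 by 1.35 ± 0.13. Rcan1 was at -0.24 ± 0.17 and did not pass. Il2 was left with 2 counts in one CsA library and 0 in the other, at or below the floor of 3 counts. On the Erk list 4 of 20 genes fell and 2 rose, or 4 and 3 adjusted over the list alone (camera, adjusted p = 0.623). Spry1 fell by 2.87 ± 0.14, Myc fell by 0.94 ± 0.12 and Dusp5 rose by 1.72 ± 0.11. Of 19 cytokines 10 fell and 4 rose, or 11 and 4 adjusted over the list alone (camera, adjusted p = 0.00580; adjusted p = 0.748 with an estimated correlation). Ccl5, a chemokine of effector and memory cells, was among those that rose, from 9.02 ± 1.51 to 72.4 ± 12.4 CPM.

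Interferon-response genes rose with CsA: 19 of 23 members and none in the other direction, or 21 and none adjusted over the list alone (median 1.94; camera, adjusted p = 1.87e-09; adjusted p = 0.306 with an estimated correlation). Oas3, an antiviral enzyme, reached 82.1 ± 4.86 CPM (log2 fold change 2.90 ± 0.16), Ifit3 rose by 4.58 ± 0.40, and Rtp4 by 4.20 ± 0.50. Of the 8 dendritic cell markers tested none passed edgeR's test (none adjusted over the list alone; camera, adjusted p = 0.623), 2 had an unadjusted p below 0.05 and DESeq2 called 1; Cd74 was at -0.14 ± 0.19. Of 6 myeloid markers 1 rose (1 adjusted over the list alone; camera, adjusted p = 0.263): Itgam, with 6 counts over both DMSO libraries and 51 with CsA. The NK list rose in 3 of 4 tested members (3 adjusted over the list alone; camera, adjusted p = 0.000607; adjusted p = 0.306 with an estimated correlation). These were Klrd1, Klrc2 (5.15 ± 0.37) and Klrk1 (2.87 ± 0.37), receptor chains that some CD8+ T cells also express.

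Naive and memory genes rose with CsA in 12 of 22 cases and fell in 3, or 14 and 3 adjusted over the list alone (median 0.78; camera, adjusted p = 0.00128; adjusted p = 0.748 with an estimated correlation). S1pr1 rose by 4.79 ± 0.31, Klf2 by 3.59 ± 0.19 and Satb1 by 2.14 ± 0.12. The granzymes Gzma (3.94 ± 0.36) and Gzmb (2.99 ± 0.36) and the granzyme inhibitor Serpinb9 (2.37 ± 0.14) rose. Of 12 cytotoxic genes 6 rose and 2 fell, or 6 and 5 adjusted over the list alone (camera, adjusted p = 0.547). Among inhibitory receptors 7 of 16 fell and 6 rose, or 7 and 7 adjusted over the list alone (camera, adjusted p = 0.489). Lag3 fell by 2.95 ± 0.16 and Havcr2 rose by 6.04 ± 0.41. Ribosome biogenesis genes fell, 20 of 26 and 25 adjusted over the list alone, with none rising (median -0.59; camera, adjusted p = 6.59e-10; adjusted p = 0.695 with an estimated correlation). Of 23 Atf4 and amino acid genes 2 fell and 1 rose, or 2 and none adjusted over the list alone (camera, adjusted p = 0.125). With an estimated correlation camera gave an adjusted p of 0.843, and 0.849 with the replicate block as well. This list passed with the replicate block (adjusted p = 0.0433) and without DMSO replicate 1 (0.00282) or CsA replicate 2 (0.00115).

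CsA raised 1595 genes and lowered 1290 of 13734, of which 876 and 313 changed by over 2-fold. Without DMSO replicate 1 the counts were 825 and 396 and without DMSO replicate 2 858 and 508. The lowered genes numbered 779 without CsA replicate 1 and 1956 with the replicate number as a block.

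**Figure D2:**
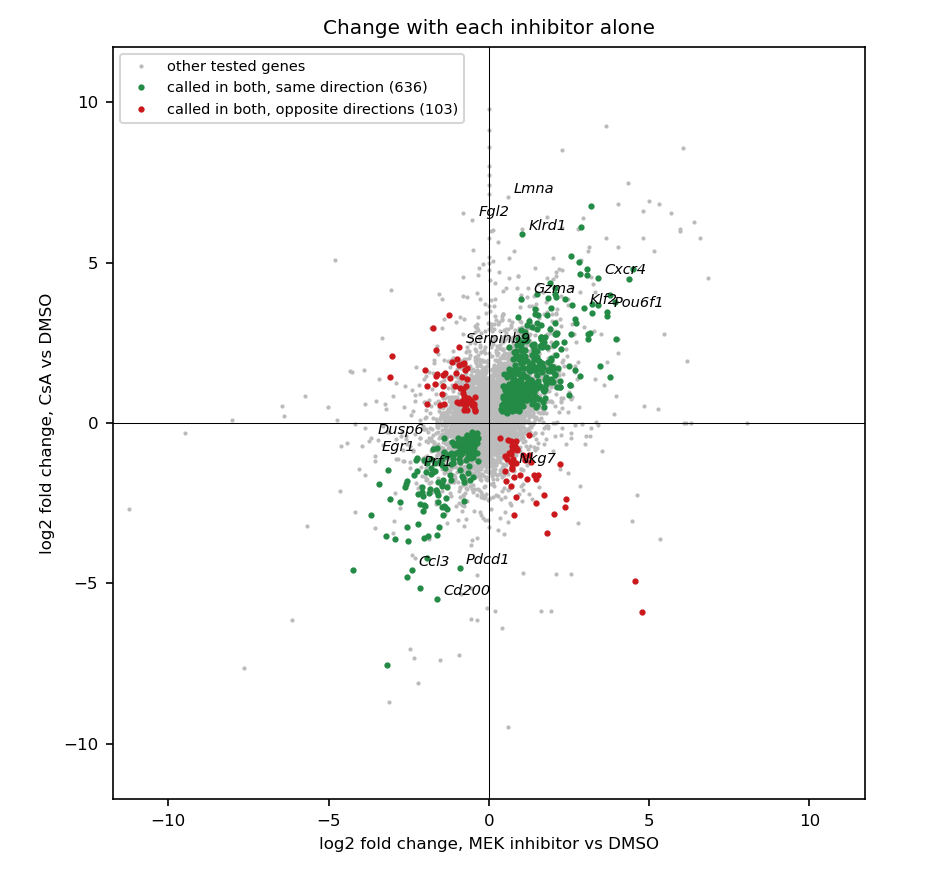
Log2 fold change with the MEK inhibitor alone (x axis) and with CsA alone (y axis) for each of 13734 genes. The 636 genes past the test in both in the same direction are green and the 103 genes past it in opposite directions are red.

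Compared directly, trametinib left Dusp6 lower than CsA did (log2 difference -3.21 ± 0.58) and Pdcd1 higher (3.61 ± 0.20; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00618 and 2.39e-05). On the Erk list 12 of 20 genes were lower with trametinib and 2 higher, or 14 and 2 adjusted over the list alone (camera, adjusted p = 2.56e-05; adjusted p = 0.439 with an estimated correlation). Spry1 was among the higher (1.45 ± 0.14). On the NFAT list 8 of 19 were higher with trametinib and 2 lower, or 10 and 5 adjusted over the list alone (camera, adjusted p = 0.443). Nr4a3 was at 3.70 ± 0.24 and Ifng at 2.68 ± 0.24. Interferon genes were lower with trametinib than with CsA, 12 of 23 with none higher, or 14 and 1 adjusted over the list alone (camera, adjusted p = 2.56e-05; adjusted p = 0.439 with an estimated correlation). On the NK list 3 of 4 genes were lower with trametinib and none higher, or 4 and none adjusted over the list alone (camera, adjusted p = 0.000146; adjusted p = 0.439 with an estimated correlation). Of 26 ribosome biogenesis genes 3 were higher with trametinib and none lower, the same adjusted over the list alone (camera, adjusted p = 9.69e-05; adjusted p = 0.850 with an estimated correlation). Of 19 cholesterol genes 8 were lower with trametinib, also 8 adjusted over the list alone (camera, adjusted p = 0.0378; adjusted p = 0.850 with an estimated correlation). The cholesterol list missed the threshold with the replicate block (adjusted p = 0.0551) and without DMSO replicate 1 (0.0626), DMSO replicate 2 (0.0628), trametinib replicate 1 (0.111) or CsA replicate 2 (0.262).

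In all, 925 genes were higher and 1244 lower with trametinib than with CsA. The higher genes numbered 510 without trametinib replicate 1, 363 without trametinib replicate 2, 604 without CsA replicate 2 and 1522 with the replicate number as a block. The lower genes numbered 764 and 577 without trametinib replicate 1 or 2.

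Each inhibitor on its own raised 427 genes that the other also raised, among them Klf2, S1pr1 and Cxcr4. In the same way they lowered 209 in common, among them Cd200, Ccl3, Ccl4 and Spry1, while 103 went in opposite directions. Independent lists of the same sizes would share 84.9, 45.3 and 125 genes. In 20 simulations of unchanged groups with a shared DMSO group the means were 0.150, 0 and 0. Unchanged groups gave few or no calls, so these means were bound to be near 0 and are no yardstick for the overlap. The covariance of the log2 fold changes was 0.292, against a mean of 0.0948 in the simulations, whereas Pearson's r was 0.429, below the simulated mean of 0.484. The simulated r comes from noise in the shared DMSO group alone, so the values of r cannot be compared directly. With trametinib set against DMSO replicate 1 and CsA against DMSO replicate 2, so that no library was shared, 119 genes rose and 40 fell with each, where independent lists would share 14.0 and 4.38, and 23 went in opposite directions, against 15.8. The other way round 132 rose, 42 fell and 27 went in opposite directions, against 14.7, 5.22 and 17.5, and Pearson's r was 0.209 and 0.250. Both fits were chosen after seeing the data, and each leaves a lone DMSO library per comparison, assumed to vary like the other groups. Without DMSO replicate 1 the shared counts were 132 and 38 and without DMSO replicate 2 136 and 44. Without trametinib replicate 1 they were 212 and 106, without trametinib replicate 2 193 and 60, and with the replicate number as a block 678 and 444.

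With both inhibitors Ccl3, Egr2 and Lif were lower than with DMSO, and Klf2, S1pr1 and Pou6f1 higher. Ccl3 went from 257 ± 28.7 to 0.648 ± 0.416 CPM, a log2 fold change of -8.67 ± 0.51 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.43e-05). Egr2 had 7 counts over both libraries against 2578 in DMSO (-8.34 ± 0.72). Lif, a cytokine, fell by 6.67 ± 0.60, Dusp6 by 5.33 ± 0.66, Pdcd1 by 5.02 ± 0.21, Ifng by 4.73 ± 0.30 and Prf1 by 3.70 ± 0.28. Klf2 reached 249 ± 5.03 CPM (4.06 ± 0.19) and S1pr1 102 ± 16.0 CPM (5.58 ± 0.32). Pou6f1, a POU-domain transcription factor, rose by 6.27 ± 0.35 and Bmf, a pro-death member of the Bcl2 family, by 5.33 ± 0.43.

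Against DMSO, 15 of 20 Erk-list genes fell with the combination and 1 rose, the same counts adjusted over the list alone (median -3.61; camera, adjusted p = 2.74e-07; adjusted p = 0.260 with an estimated correlation). Of 19 NFAT targets 15 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -2.76; camera, adjusted p = 1.61e-09; adjusted p = 0.260 with an estimated correlation). Il2 had 2 and 0 counts. Cytokines fell in 12 of 19 cases and rose in 3, or 13 and 3 adjusted over the list alone (camera, adjusted p = 5.35e-05; adjusted p = 0.365 with an estimated correlation). Of 18 activation surface proteins 8 fell and 2 rose, or 11 and 2 adjusted over the list alone (camera, adjusted p = 0.00384; adjusted p = 0.365 with an estimated correlation). Inhibitory receptors fell in 9 of 16 cases with 3 rising, or 10 and 4 adjusted over the list alone (camera, adjusted p = 0.0240; adjusted p = 0.431 with an estimated correlation). All 26 ribosome biogenesis genes fell, also 26 adjusted over the list alone (median -0.90; camera, adjusted p = 7.48e-11; adjusted p = 0.365 with an estimated correlation). Polr1b, an RNA polymerase I subunit, fell by 1.18 ± 0.12. Of 18 glycolysis genes 9 fell and none rose, the same adjusted over the list alone (camera, adjusted p = 0.000877; adjusted p = 0.449 with an estimated correlation), and Hk2, a hexokinase, fell by 1.16 ± 0.19.

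Naive and memory genes rose in 13 of 22 cases and fell in 1, the same adjusted over the list alone (median 0.82; camera, adjusted p = 4.70e-05; adjusted p = 0.365 with an estimated correlation). Interferon genes rose in 17 of 23 cases, also 17 adjusted over the list alone (median 1.43; camera, adjusted p = 9.63e-08; adjusted p = 0.260 with an estimated correlation). Oas3 rose by 2.71 ± 0.16. Of 6 myeloid markers 1 rose and none fell, the same adjusted over the list alone (camera, adjusted p = 0.497). Of 8 dendritic cell markers 1 rose and 1 fell, or 1 and none adjusted over the list alone (camera, adjusted p = 0.7245). On the NK list 3 of 4 genes rose and none fell, the same adjusted over the list alone (median 1.77; camera, adjusted p = 0.0124; adjusted p = 0.365 with an estimated correlation; 0.0639 without combination replicate 2). They were Klrd1 (5.01 ± 0.24), Klrk1 (1.90 ± 0.37) and Klrc2, which missed the threshold without DMSO replicate 1 (adjusted p = 0.0793), DMSO replicate 2 (0.0675) or combination replicate 1 (0.0818) and with length-scaled counts (0.103). Mitosis genes rose in 12 of 24 cases with none falling, or 14 and 1 adjusted over the list alone (median 0.42; camera, adjusted p = 0.000346; adjusted p = 0.365 with an estimated correlation). Ccnb2, a mitotic cyclin, rose by 1.06 ± 0.11. By comparison 2 of 28 DNA replication genes rose and 2 fell, the same adjusted over the list alone (camera, adjusted p = 0.774). Of 15 T cell identity genes 8 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.0124; adjusted p = 0.365 with an estimated correlation), with Cd8b1 at 1.26 ± 0.11. Of 6 B cell markers 2 rose, also 2 adjusted over the list alone (camera, adjusted p = 0.0401; adjusted p = 0.415 with an estimated correlation), Ighm by 1.21 ± 0.11 and Cd79b by 1.71 ± 0.33. None of 6 red cell and platelet genes passed edgeR's test (none adjusted over the list alone; camera, adjusted p = 0.749), 1 had an unadjusted p below 0.05 and DESeq2 called 0. Of 4 CD4 and regulatory T cell markers 3 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.203). That list passed without trametinib replicate 1 or 2 (adjusted p = 0.0412 and 0.0410) and with no filter on low counts (0.0435).

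**Figure D3:**
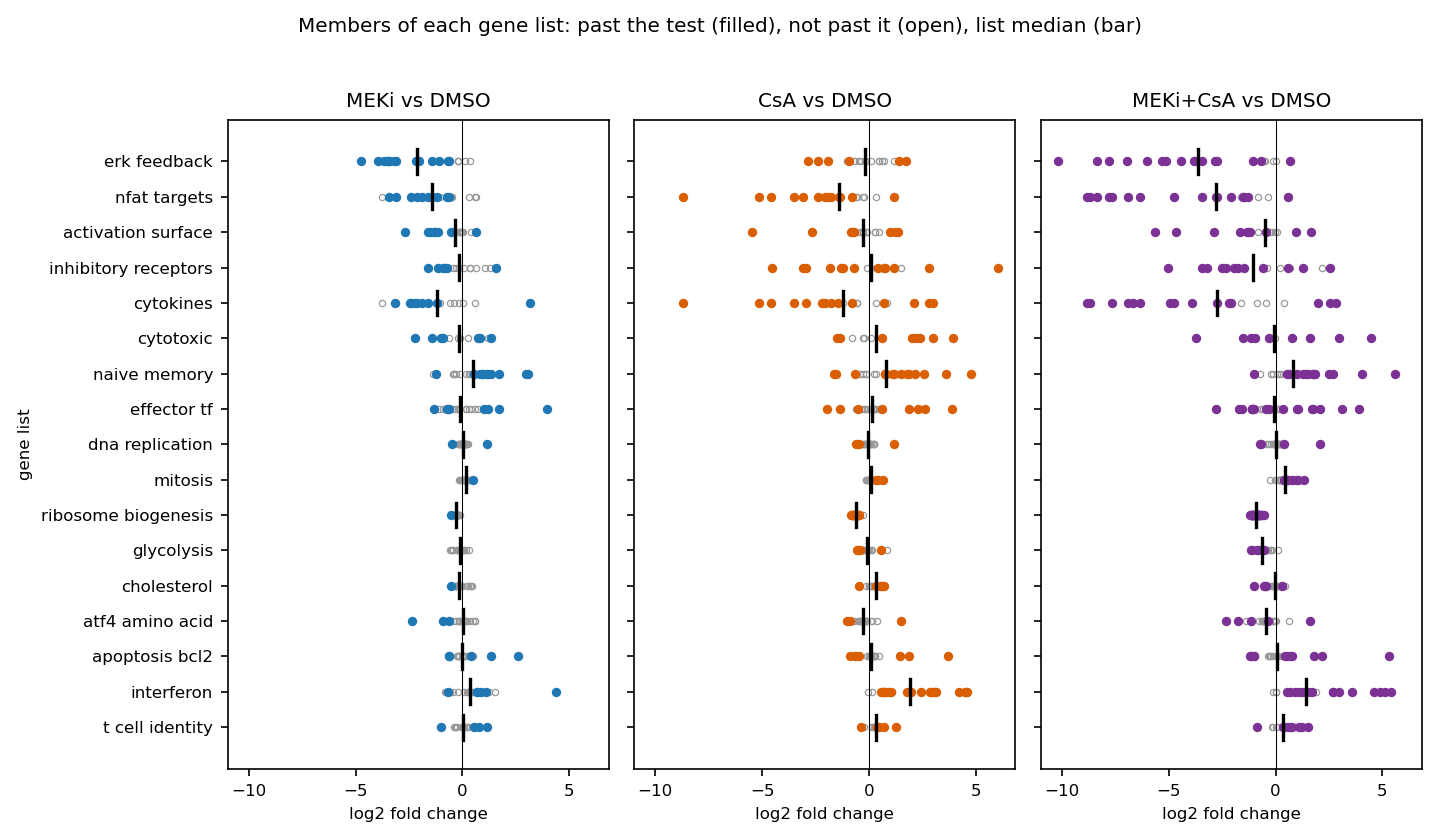
Log2 fold change against DMSO of the members of 17 gene lists with the MEK inhibitor (MEKi), CsA or both. Filled points passed the test, open points did not, and bars mark list medians, which lay at -2.10, -0.17 and -3.61 for the Erk list and at 0.35, 1.94 and 1.43 for the interferon list.

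The combination raised 2370 genes and lowered 2365 of 13734, of which 1241 and 690 changed by over 2-fold. Of those raised, 418 had also risen with each inhibitor alone, 840 with CsA and not trametinib, 187 with trametinib and not CsA, and 925 with neither. Of those lowered the numbers were 204, 889, 189 and 1083. Passing one test and missing another is not a tested difference. Of the 840 and 187 raised genes, 481 and 97 differed between the inhibitors in the direct test, as did 357 and 132 of the 889 and 189 lowered genes. Moreover 33 of all raised and 16 of all lowered genes passed the interaction test. Without DMSO replicate 1 the combination raised 1429 and lowered 1319, and without DMSO replicate 2 it raised 1499 and lowered 1417.

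Adding CsA to trametinib lowered Ifng, Ccl4, Lag3 and Pdcd1 and raised Klrd1 and Ifit3. Relative to trametinib alone, Ifng fell by 5.33 ± 0.30, Ccl4 by 5.74 ± 0.39 and Lag3 by 3.56 ± 0.16, and Pdcd1 had a log2 fold change of -4.10 ± 0.20. Klrd1 rose by 3.96 ± 0.22 and Ifit3 by 4.22 ± 0.37 (edgeR's quasi-likelihood test, adjusted p = 3.60e-05 for Klrd1). Of 19 NFAT targets 13 fell and 1 rose, the same adjusted over the list alone (median -2.15, or -1.11 with genes below the floor set to their bound; camera, adjusted p = 3.23e-07; adjusted p = 0.339 with an estimated correlation). Of 23 interferon genes 13 rose and none fell, or 14 and none adjusted over the list alone (camera, adjusted p = 3.01e-08; adjusted p = 0.339 with an estimated correlation). Of 4 NK-list members 2 rose, or 4 adjusted over the list alone (camera, adjusted p = 0.00235; adjusted p = 0.367 with an estimated correlation). The 2 were Klrd1 and Klrk1 (1.81 ± 0.37; adjusted p = 0.0805 without trametinib replicate 1), whereas Klrc2 was at 1.01 ± 0.38 and did not pass. Of 6 B cell markers 1 rose, also 1 adjusted over the list alone (camera, adjusted p = 0.0343; adjusted p = 0.404 with an estimated correlation). It was Ighm, by 0.61 ± 0.10, which missed the threshold without trametinib replicate 1 (adjusted p = 0.0502) or 2 (0.0674). The dendritic cell markers lay higher as a group (median 0.55; camera, adjusted p = 0.0483; adjusted p = 0.404 with an estimated correlation). None of the 8 passed edgeR's test, also none adjusted over the list alone, 2 had an unadjusted p below 0.05 and DESeq2 called 0. That list missed the threshold without trametinib replicate 2 (0.151) or combination replicate 2 (0.132), with the replicate block (0.0615), with DESeq2 size factors (0.0522) and with length-scaled counts (0.102). The Erk list also fell when CsA was added to trametinib, in 8 of 20 genes with 1 rising, the same adjusted over the list alone. Its median was -1.50 (camera, adjusted p = 0.00209, or 0.404 with an estimated correlation). Ribosome biogenesis genes fell in 19 of 26 cases, or 25 adjusted over the list alone (camera, adjusted p = 1.85e-10, or 0.404 with an estimated correlation). In this comparison 13 of 23 lists passed camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.339). Of 2885 genes that changed with CsA alone, 2739 (94.9%) moved in the same direction with trametinib present, 1698 of them past the test, and 16 passed it in the opposite direction. Across all genes, which are not independent replicates, Pearson's r was 0.624 and Spearman's rho 0.652. In all 1252 genes rose and 1163 fell. Without trametinib replicate 1 these counts were 648 and 471 and without trametinib replicate 2 477 and 403. Without combination replicate 1 they were 711 and 592, and 1887 fell with the replicate number as a block.

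Adding trametinib to CsA lowered the Erk list: 15 of 20 genes fell and none rose, or 18 and none adjusted over the list alone (median -3.22; camera, adjusted p = 1.72e-15; adjusted p = 0.158 with an estimated correlation). Dusp6 fell by 4.87 ± 0.65, Dusp4 by 4.14 ± 0.52 and Rgs2, a regulator of G protein signalling, by 4.52 ± 0.23 (edgeR's quasi-likelihood test, adjusted p = 0.00324 for Dusp6). The cytotoxic-cell gene Nkg7 rose by 2.12 ± 0.12. Some genes that had risen with CsA alone fell, such as Havcr2 by 3.51 ± 0.33, Klrc2 by 3.51 ± 0.33, Serpinb9 by 3.33 ± 0.14 and Serpinb6b by 3.16 ± 0.26. Such a fall was not called for all of the 1595 genes raised by CsA alone, since 575 genes of any kind fell when trametinib was added. With both inhibitors, 418 of the 1595 that trametinib alone also raised and 840 that it did not were still called above DMSO. A call above DMSO does not show that a gene kept its level with CsA: Klrc2 fell and was still called above DMSO. On the NFAT list 7 of 19 genes fell and none rose, or 10 and none adjusted over the list alone (median -1.16; camera, adjusted p = 1.91e-08; adjusted p = 0.212 with an estimated correlation). Egr2 fell by 6.44 ± 0.75 and Ifng by 2.66 ± 0.31, whereas Nfatc1 (-0.06 ± 0.18) and Gzmb (-0.05 ± 0.33) did not pass the test. On the NK list 2 of 4 genes fell and none rose, or 3 and none adjusted over the list alone (camera, adjusted p = 0.00713; adjusted p = 0.365 with an estimated correlation), and the list missed the threshold without combination replicate 1 (0.103) and with no filter on low counts (0.104). They were Klrc2 and Klrd1 (-0.90 ± 0.18), which missed the threshold without combination replicate 1 (adjusted p = 0.107) or CsA replicate 2 (0.105), with length-scaled counts (0.0554) and with the compared groups alone in the fit (0.0548). Here 12 of 23 lists passed camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.158). Of 1213 genes that changed with trametinib alone, 1098 (90.5%) moved in the same direction with CsA present, 540 of them past the test, and 9 passed it in the opposite direction. Across all genes Pearson's r was 0.435 and Spearman's rho 0.486. In all 501 genes rose and 575 fell. The rising genes numbered 321 and 318 without DMSO replicate 1 or 2, 182 without CsA replicate 2 and 203 without combination replicate 1. The falling genes numbered 317 without CsA replicate 2 and 313 without combination replicate 1, and with the replicate number as a block 1005 rose and 1012 fell.

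The interaction asks whether the combined change differed from the sum of the single changes on the log2 scale. It was negative for 60 genes and positive for 10 of 13734, and 51 of the 60 had risen with CsA alone and 34 with trametinib alone. The term is computed from the same libraries, and a negative value favours genes that are high with either inhibitor alone. These counts, and those that follow, are thus partly set by the selection. In 28 of the 60 each inhibitor alone had raised the gene, as for Klf2, which stood at 14.8, 115, 180 and 249 CPM with DMSO, trametinib, CsA and both (interaction -2.48 ± 0.24; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00824). Of these 28 genes 22 were also above DMSO with both. In 29 of the 60 the gene rose with CsA and fell when trametinib was added, as for Serpinb9 (chromosome 13, 33003250 to 33017957, GRCm38), which stood at 47.6 ± 0.175, 25.2 ± 4.76, 246 ± 21.9 and 24.4 ± 0.610 CPM in the same order (-2.41 ± 0.19). In 12 of the 60 the gene rose with trametinib and fell when CsA was added. Of the 51 that rose with CsA alone, CsA added to trametinib raised 19, lowered 11 and left 21 without a call. Fgl2, a fibrinogen-like protein of T cells, and Klrc1, a partner chain of Klrd1, both chosen after their values were seen, gave -3.92 ± 0.35 and -3.75 ± 0.41, with mean CPM of 102 and 29.4 with CsA and 4.70 and 2.24 with both. Klf2, Serpinb9, Fgl2, Klrc1, Ifng and Cxcr4 kept the call without any 1 library. For Ifng the interaction was -3.26 ± 0.38.

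On the Erk list no gene passed edgeR's interaction test, 10 had an unadjusted p below 0.05, DESeq2 called 2, and 2 lay lower adjusted over the list alone. The list median was -1.27 (camera, adjusted p = 0.00307; adjusted p = 0.816 with an estimated correlation; adjusted p = 0.129 without trametinib replicate 1). On the NK list 2 of 4 genes lay lower, Klrd1 and Klrc2, also 2 adjusted over the list alone (camera, adjusted p = 0.00520; adjusted p = 0.816 with an estimated correlation). That list missed the threshold without combination replicate 1 (0.123) and with no filter on low counts (0.183). Klrc2 missed it without DMSO replicate 1 (adjusted p = 0.112) or 2 (0.110), trametinib replicate 2 (0.0900) or CsA replicate 1 (0.0563) or 2 (0.0615). Klrd1 missed it without any library other than combination replicate 2 (up to 0.255), and both missed it with length-scaled counts. The cholesterol list lay lower (median -0.24; camera, adjusted p = 0.00951; adjusted p = 0.816 with an estimated correlation) and the mitosis list higher (median 0.13; camera, adjusted p = 0.0416; adjusted p = 0.816 with an estimated correlation). No gene of either passed edgeR's test, also none adjusted over the list alone, 1 and 0 had an unadjusted p below 0.05 and DESeq2 called 0. The cholesterol list missed the threshold without DMSO replicate 2 (0.0779), trametinib replicate 2 (0.0637), CsA replicate 2 (0.149) or combination replicate 1 (0.264) and with no filter on low counts (0.0541). The mitosis list missed it without DMSO replicate 1 (0.0740) or 2 (0.0780), trametinib replicate 1 (0.0657) or 2 (0.0637), CsA replicate 2 (0.348) or combination replicate 1 (0.194). On the Bcl2 family list no gene passed, 3 had an unadjusted p below 0.05, DESeq2 called 3, and 1 lay higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.919). The interaction held 1175 genes at an unadjusted p below 0.05. Negative and positive calls numbered 14 and 2 without DMSO replicate 1, 9 and 1 without DMSO replicate 2, 27 and 9 without trametinib replicate 1 and 29 and 5 without trametinib replicate 2. They numbered 17 and 3 without CsA replicate 1, 34 and 6 without CsA replicate 2 and 35 and 5 without combination replicate 1, and 212 and 74 with the replicate number as a block, which kept all 70.

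**Figure D4:**
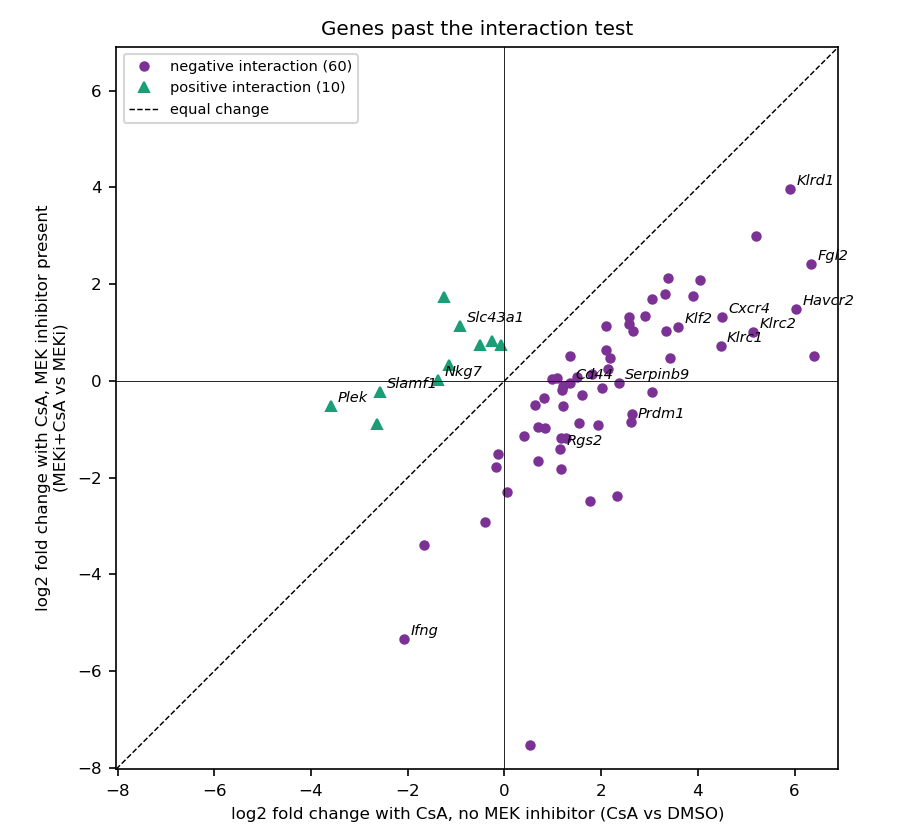
Log2 fold change with CsA in the absence of the MEK inhibitor (x axis) and in its presence (y axis) for the 70 genes past the interaction test. The 60 negative genes (circles) lie below the line of equal change and the 10 positive genes (triangles) above it.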

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

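The 2 tests of explanations in this part were chosen after the result was seen, whereas the interaction test itself was fixed before the files were read. The interaction test found that the trametinib change on the log2 scale differed with and without CsA (edgeR's quasi-likelihood test, n = 2 libraries per group). The term was negative for 60 genes and positive for 10. A negative term on this scale need not mean a smaller change in CPM, and changes in CPM were not tested. The genes below are among those that the naming rule took, with their interaction terms on the log2 scale.

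Negative terms whose calls held without any 1 library were those of Ifng (-3.26), Cxcr4 (-3.19), Klf2 (-2.48) and Serpinb9 (-2.41). Emp1 (-2.86) missed the threshold without CsA replicate 1 or DMSO replicate 2, with an adjusted p of up to 0.0596. Rgs2 (-2.58) and Gucy1a1 (-2.41) missed it without DMSO replicate 1 or 2, with up to 0.0874 and 0.0515. Itih5 (-2.35) missed it without DMSO replicate 1 or 2, trametinib replicate 1 or 2, CsA replicate 1 or combination replicate 2 (up to 0.166).

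Of the positive terms, Plek (3.06) missed the threshold without CsA replicate 1 (adjusted p = 0.0516). Slamf1 (2.34) missed it without DMSO replicate 1 or 2 or CsA replicate 1, Slc43a1 (2.04) without trametinib replicate 1, CsA replicate 1 or DMSO replicate 2, and Nkg7 (1.39) without DMSO replicate 1 or 2 or trametinib replicate 1 or 2, each with an adjusted p of up to 0.0874. Pros1 (1.74) missed it without DMSO replicate 1 or 2, trametinib replicate 2, CsA replicate 1 or 2 or combination replicate 1 (up to 0.138), and Acss1 (1.48) and Il21r (1.26) without any library other than combination replicate 2 (up to 0.168).

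Of the 60 genes with a negative term 51 had risen with CsA and 34 with trametinib, and CsA added to trametinib raised 19 of the 51, lowered 11 and left 21 without a call. The same libraries enter the term and these counts, so the counts are partly set by the selection and are no separate evidence. NK cells in the CsA cultures would have brought their other transcripts: the summed counts of Ncr1, Klrb1c, Tyrobp and Fcer1g gave a CsA to DMSO ratio of 1.203 (0.812 to 1.78, counting error), against a rise of over 5-fold in Klrk1, Klrc2 and Klrd1, which argues against them. Low counts that bend the log scale would need most of the 51 genes near the floor, and 15.69% (8 of 51; 7.02 to 28.6) had under 1 CPM in their lowest group, which argues against that as the general account. The low-count test was narrowed to these 51 genes after a first value over more genes had been seen, with the same outcome. A need for Erk activity stays open, as an untested hypothesis, for the 29 of these genes that fell when trametinib was added to CsA, as does a need for calcineurin for the 12 genes that rose with trametinib and fell when CsA was added, but not for the level of genes such as Klf2, which stood at 180 CPM with CsA and 249 CPM with both.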

How the results depend on the processing

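With the replicate number as a block, trametinib raised 1170 and lowered 937 genes, CsA lowered 1956, the combination lowered 1887 against trametinib and raised 1005 and lowered 1012 against CsA, 1522 were higher with trametinib than with CsA, the interaction had 74 positive and 212 negative genes, and 678 and 444 were higher and lower with each single inhibitor. The block kept 1213 of 1213, 2884 of 2885, 4732 of 4735, 2415 of 2415, 1076 of 1076, 2169 of 2169 and 70 of 70 calls of the 7 comparisons. Of the named genes it ended no call and made 14: Nfatc1, Cd79b and Cd40lg with trametinib (adjusted p = 0.00817, 0.0144 and 0.0334), Klrc1 with the combination against DMSO and against trametinib (0.0195 and 0.0367), Il2ra, Tcf7, Cd79b and Klrk1 with the combination against CsA (0.0153, 0.00378, 0.0350 and 0.000555), Rcan1, Egr2 and Cd68 between trametinib and CsA (0.0332, 0.0112 and 0.0449), and Gzmb and Klrk1 in the interaction (0.0168 each). Among lists it made the calls of the Atf4 list with CsA (0.0433), with the combination (0.0170) and for the combination against trametinib (0.0415) and of glycolysis in the interaction (0.0163), and ended those of cholesterol between trametinib and CsA (0.0551) and of dendritic cell markers for the combination against trametinib (0.0615).

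With trametinib against DMSO replicate 1 and CsA against DMSO replicate 2, chosen after the data were seen, 119 and 40 were higher and lower with each single inhibitor, and 132 and 42 the other way round. Fits of the compared groups alone gave 1264 and 1225 genes with trametinib, 189 and 334 for the combination against CsA, and 482 lower with each single inhibitor. The spread shared by all groups gave 731 and 482 with trametinib and 501 and 575 for the combination against CsA. Replicates differed more with CsA and the combination (chi-square per degree of freedom 41.0 and 36.4) than with DMSO and trametinib (11.6 and 10.2). Equal spread in all groups is therefore not given. Length-scaled counts gave 282 lower with trametinib, 834 lower with CsA, 762 lower for the combination against trametinib, 293 and 380 against CsA, 5 and 25 for the interaction and 102 lower with each single inhibitor. Without a filter on low counts 873 were lower with trametinib, 1029 and 924 changed for the combination against CsA, 154 and 323 in the interaction and 404 were lower with each single inhibitor, and 88.77% kept the sign of the trametinib change. DESeq2 called 62 and 187 interaction genes. Among calls of named genes, length-scaled counts ended 62, and fits of the compared groups alone ended 34 and made 4. Dropping the filter on low counts ended 3 and made 22. DESeq2 ended 2 and made 6, and its size factors within edgeR ended 2. The cause of these shifts was not tested. Estimating the correlation, which also cuts the degrees of freedom of camera, gave adjusted p = 0.312 for the Erk list with trametinib (0.727 with the block). For the NFAT list with CsA camera gave 0.306 (0.513 with the block), and no list passed in any comparison.

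Leaving out 1 library, which leaves 3 residual degrees of freedom in place of 4, gave these lowest and highest counts, higher then lower: trametinib 231 to 797 and 128 to 611; CsA 825 to 1695 and 396 to 1562; combination 1429 to 2474 and 1319 to 2483; combination against trametinib 477 to 1294 and 403 to 1301; combination against CsA 182 to 492 and 313 to 579; trametinib against CsA 363 to 1130 and 577 to 1325; interaction 1 to 14 and 9 to 46; each single inhibitor 132 to 458 and 38 to 284. The shares that kept their sign ranged from 88.87 to 93.01% and from 93.19 to 97.07%. For ribosome biogenesis in the interaction the direction turned, with an adjusted p of 0.0201 without combination replicate 2 (0.846 with all libraries, and 0.0116 to 0.974 over all libraries left out in turn). The lone library of a group is assumed to vary like the other groups. The second file of each library and DESeq2 size factors moved no count by over 1.5 times.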

Other observations

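The test of other cell types for the interferon genes was chosen after the result was seen, whereas the predictions for the 2 trametinib libraries were written before their tests, as far as stated below.

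On the Bcl2 family list with both inhibitors 7 of 19 genes rose and 4 fell, or 7 and 6 adjusted over the list alone (camera, adjusted p = 0.751). Bcl2l11, which encodes the pro-death protein Bim, rose by 1.36 ± 0.16 with trametinib, 1.85 ± 0.17 with CsA and 2.17 ± 0.17 with both on the log2 scale (edgeR's quasi-likelihood test, n = 2 libraries per group). Bcl2a1b, a survival gene of activated lymphocytes, fell by 2.56 ± 0.30 with trametinib.

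The trametinib libraries differed in Erk-target transcripts, replicate 1 keeping more of them. Carry-over of DMSO material would give 1 fraction for all genes. This fraction is the distance of replicate 1 from replicate 2, divided by that of the DMSO mean from replicate 2. Over 66 lowered genes, at most 0.2 of the DMSO mean in replicate 2, its median was 0.167 (quartiles 0.114 and 0.244). Its interquartile range was 0.1305 (0.0928 to 0.164). Over 42 raised genes the matching median was 0.2976 (0.156 to 0.375), above that upper quartile, with an interval reaching below it. This leaves carry-over open. Choosing genes by replicate 2 favours a replicate 1 closer to DMSO. Chosen by replicate 1 instead, 21 lowered genes gave replicate 2 a median of -0.103, still further from DMSO. A weaker block of Erk would keep more of the Erk list: its median fraction was 0.116 (9 genes) against 0.180 (57 genes), a difference of -0.06402 (permutation p = 0.0987, interval -0.108 to 0.00249). This met the bound written against that explanation, but the bound was wrong, since the comparison genes also fell with trametinib and a weaker block moves them too, so the 2 explanations cannot be told apart. The values of Dusp6, Egr1, Egr2 and Il2 were seen before the predictions, and the one for raised genes was written after the fractions of lowered genes were seen.

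Of 23 interferon-response genes 19 rose with CsA, or 21 adjusted over the list alone (camera, adjusted p = 1.87e-09; adjusted p = 0.306 with an estimated correlation, and 0.513 with the replicate block as well). Dendritic or myeloid cells would bring their abundant transcripts. The median log2 change of Cd74, H2-Aa, H2-Ab1, Lyz2, Fcer1g and Cd68 was 0.1417 and their summed CsA to DMSO ratio 0.962 (0.898 to 1.03, 1489 and 1861 counts). This argues against more such cells as the source of the interferon-response transcripts themselves. Most of the summed counts were those of Cd74, so the ratio rests mainly on that gene, and its interval covers counting error only. The set leaves out Itgam, the myeloid marker that rose. The fixed myeloid and dendritic lists had medians of 0.52 and 0.36 (camera, adjusted p = 0.263 and 0.623). Signals from a few such cells to the T cells are not covered by the test. A response of the T cells to interferon stays open as a hypothesis. Ifng, the interferon transcript tested here, fell with CsA by 2.08 ± 0.24 on the log2 scale (edgeR's quasi-likelihood test, adjusted p = 0.000600), which runs against more interferon gamma from these cells at the time of sampling.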
